A study of Homo sapiens with 6 samples.

How the data were processed

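RNA was measured by sequencing in HEK293 cells, a human embryonic kidney line, that stably expressed tensin 2 (TNS2) with tyrosine 483 replaced by glutamate (Y483E) or by phenylalanine (Y483F). Each of the 2 groups had 3 libraries, 6 in all. The libraries were made from total RNA after selection with poly-T beads. The protocol text names a directional and a non-directional way of making the second strand, so the strandedness of the libraries is not known. Where genes overlap on opposite strands, reads of one can have been counted at the other.

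Per the submitters' processing notes, the tools were HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 and DESeq. The notes do not say what each tool was used for, and the genome build is not given in the sources used here. Of the 58735 genes in the authors' table, 58690 had the chromosome, start, end and strand of GENCODE 29 gene models on GRCh38, from which GC content was taken. Biotypes, positions and gene lengths are those of the authors' table. One deposited table holds FPKM values for every gene with its length. The other deposited table holds the authors' comparison of Y483E with Y483F for 1652 genes. For these genes it gives the authors' raw read counts, the same FPKM values as the first table, and the signal made by dividing the authors' counts by 1 size factor per library, with its group means. It also gives the authors' log2 fold changes of Y483E over Y483F and the authors' unadjusted and adjusted p-values. The largest unadjusted p-value listed was 0.04999. The library total behind the deposited FPKM values was proportional to the size factor and was not the sum of the reads.

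Multiplying FPKM by gene length and by that library total gave whole numbers, within 0.01 of a read, for 100% of the values above 0. The total of each library was worked out from the listed counts and FPKM values of the 1652 genes. A match with these counts was therefore largely built in. The recovered reads equalled the authors' listed counts for all 1652 genes in every library. They summed to between 17204498 and 23284592 per library, and this depth limits what could be measured for genes with few reads. A count of 0 allows up to 3 reads in a library, and this floor covers counting error only.

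The test fixed before the data were examined was limma 3.58.1 (lmFit, then eBayes with a trend) on log2(FPKM + 1), two-sided, for genes with a mean of at least 1 FPKM. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all 12833 genes tested. Fold changes are Y483E over Y483F. The gene lists, 36 with 868 members, were written before the data were examined, and the 33 lists with at least 5 tested members were compared with the other genes by camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The 23 chromosomes were tested by camera in the same way. Single values were compared by two-sided exact permutation tests, for which 0.1 is the smallest p that 3 libraries against 3 can give.

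Since whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) and DESeq2 1.42.0 were added after the data had been seen. The log2 fold changes of DESeq2 run here differed from those in the authors' table by at most 5.2e-06. Calls by the authors and by DESeq2 here are therefore not separate evidence. The submitters numbered the libraries 1, 4 and 5 in each group. The labels do not say what these numbers stand for. Number 1 is replicate 1, number 4 is replicate 2 and number 5 is replicate 3. A model with a batch term, number 1 against 4 and 5, and a comparison of the libraries numbered 4 and 5 alone were also chosen after the data had been seen, as were camera with an estimated correlation in the alternative fits and after the correction for GC content and gene length, and a test of the interaction of line and number, in which the lone libraries numbered 1 are assumed to vary like the others.

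Genes were named by a rule fixed before the data were examined. It takes the 4 tensin genes and GAPDH, and the 12 largest rises and 12 largest falls among protein-coding genes past the limma threshold, of which there were 0. For each list described by its members it takes up to 4 members past the threshold or, with fewer than 2 such members, the 2 with the highest mean FPKM. From the authors' table it takes the 3 smallest adjusted p-values in each direction. The 13 lists described by members were chosen partly after the results were seen, and the other 20 are given by their medians. Genes called by edgeR, and other genes named outside the rule, were chosen after their values were seen.

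Other settings tried were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, array weights, the replicate number as a block, voom on the recovered reads, protein-coding genes only, and leaving out each library. For edgeR they were no TMM, the size factors of DESeq2, no filter, the block and leaving out each library. The pipeline was tested on simulated data with 200 changed genes. Each gene was given the spread of the trend that edgeR fitted to these libraries by abundance. Genes that vary more than others of like abundance were therefore not simulated. Each gene was drawn independently, so differences that a library shows across many genes at once were not simulated. The real libraries show such differences, so the shares that follow may not carry over to them. Genes changed 2-fold were called in 81.6% of cases by limma, 98.0% by edgeR and 95.9% by DESeq2. At 1.5-fold these shares were 68%, 88% and 84%, and of the unchanged genes 0.0878%, 0.0894% and 0.0523% were called. A simulated shift of -0.15 on chromosome 21 was recovered as -0.147, and a shift of 0.25 on the list of ATF4 targets as 0.219. At the preset correlation camera also called 0 other chromosomes and 1 other list, which had not been shifted as a list. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. No library was left out of the stated tests.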

Results

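The data were gene expression values from 6 libraries of HEK293 cells, 3 from a line expressing tensin 2 Y483E and 3 from a line expressing tensin 2 Y483F. Glutamate at a tyrosine position is used to resemble a phosphorylated residue, and phenylalanine cannot be phosphorylated. The series title ties tensin 2, a focal adhesion protein, to GAPDH and to a control of glycolysis through phosphorylation, so the comparison of the lines asks which transcripts differ between these forms. Reads summed to 17919298, 23284592 and 18379482 in Y483E replicates 1, 2 and 3, and to 17204498, 17835265 and 20274593 in Y483F replicates 1, 2 and 3. The series text speaks of 2 cell lines and does not say whether several clones of each were used. If each form was carried by 1 line, a difference between the lines and an effect of the mutation cannot be separated. The titles call the replicates biological without stating separate cultures, so the p-values measure the spread between these samples.

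Between the lines, ABCA12 (a lipid transporter) was far lower in Y483E, most tested genes of chromosome 18 were higher, and most of those of chromosomes 20 and 21 were lower. Targets of the stress regulator ATF4 and cytosolic ribosomal protein genes had higher medians in Y483E, and mitochondrially encoded genes had lower ones, in replicates 2 and 3 but not between the replicates 1. TNS2, GAPDH and the glycolysis list showed no difference past the threshold over all 6 libraries. No single gene passed it in limma, with 0 of 12833 genes past an adjusted p of 0.05 and 1566 at an unadjusted p under 0.05. With array weights, which give the libraries unequal weight, limma called 1888 genes, 44 of them changed at least 2-fold. Among protein-coding genes, adjusted over these alone, it called 1422, of which 2 changed at least 2-fold. On the recovered reads, edgeR called 7 of 15992 genes and DESeq2 called 142, with 2142 and 1652 genes at an unadjusted p under 0.05. Of the genes called by edgeR, ABCA12, SALL3, CPNE4 and AC072062.1 had means under 1 FPKM and were not tested in the stated limma fit. With no filter limma also called 0 genes.

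The libraries did not group by line alone. On the first principal component, with 40.9% of the variance, Y483F replicate 1 lay at -5.70, among the Y483E libraries at -5.89, -4.94 and -13.4, while Y483F replicates 2 and 3 lay at 17.0 and 12.9. On the second, with 21.6%, the replicates 1 of Y483E and Y483F lay together at 9.36 and 11.5, and the other 4 between -9.03 and -0.93. By chi-square per degree of freedom between their reads, which also depends on depth, the closest libraries were Y483F replicates 2 and 3, at 2.43. Next came Y483E replicate 1 and Y483F replicate 1, from different lines, at 3.31, against 21.99 for the most distant pair. The correlation of log2 values across genes gave another order. By it Y483E replicates 2 and 3 were closest (0.9933), then Y483F replicates 2 and 3 (0.9929) and the replicates 1 (0.9917). Without Y483F replicate 1, edgeR called 1000 genes, and without Y483E replicate 1 it called 174. In the libraries numbered 4 and 5 alone, a comparison chosen after the data had been seen, limma called 733 genes (347 higher, 386 lower in Y483E) and edgeR 2454 (1153 higher, 1301 lower). With the batch term limma called 0, with 2213 at an unadjusted p under 0.05, and edgeR called 169.

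TNS2 (ENSG00000111077, chromosome 12, 53046969 to 53064372, plus strand) was measured at 0.948 ± 0.169 FPKM (SD of 3 libraries) in Y483E and 1.13 ± 0.0534 in Y483F. The log2 fold change was -0.13 ± 0.095 (SE), with an adjusted p of 0.604, on values to which a pseudocount of 1 was added, which shrinks the fold at this level. On the recovered reads edgeR gave -0.26 ± 0.15 (adjusted p 0.474), and with a pseudocount of 0.1 limma gave -0.24. Without Y483E replicate 1, the library lowest in TNS2, limma gave -0.058. Every Y483F library lay above every Y483E library, at an exact permutation p of 0.1, the smallest this design allows. The reads behind these values were 109, 197 and 156 in Y483E and 148, 169 and 191 in Y483F. Reads of the construct and of the endogenous TNS2 gene are not told apart. Among the related tensins, TNS3 had 0.615 ± 0.0865 and 0.582 ± 0.0800 FPKM, TNS1 had 0.0868 ± 0.0207 and 0.0539 ± 0.0157, and TNS4 had 0 reads in all 6 libraries.

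GAPDH, the glycolytic enzyme named in the series title (ENSG00000111640, chromosome 12, 6533927 to 6538374), was at 758 ± 21.5 FPKM in Y483E and 715 ± 58.8 in Y483F. Its log2 fold change was 0.09 ± 0.070 (SE), adjusted p 0.642, and the exact permutation p was 0.4. In the libraries numbered 4 and 5 alone, GAPDH was higher in Y483E by 0.15 ± 0.042 in edgeR (adjusted p 0.0247), while limma on these libraries gave 0.16 and did not call it (adjusted p 0.0968). Between the replicates 1 the difference was -0.052. Leaving out 1 library gave 0.042 without Y483F replicate 2 and 0.15 without Y483F replicate 1, with no call.

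**Figure D1:**
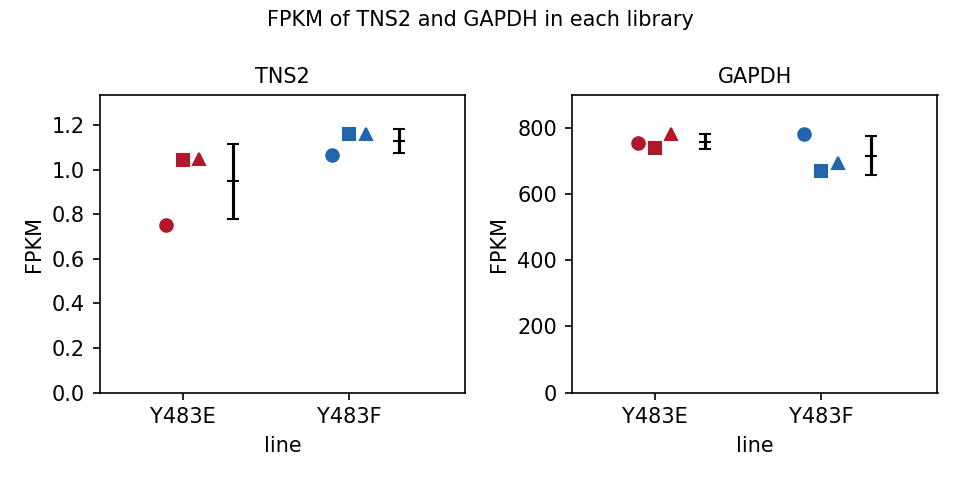
FPKM of TNS2 and GAPDH in each library of the Y483E line (red) and the Y483F line (blue); circles, squares and triangles are replicates 1, 2 and 3, and the black bars are the mean and SD of the 3 libraries. TNS2 lay near 1 FPKM in both lines, and the GAPDH values of the lines overlapped.

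Genes of glycolysis and lactate transport lay on both sides of 0, with 10 of 22 tested members higher and 12 lower in Y483E and a median log2 fold change of -0.011 (camera adjusted p 0.450). None of them passed the threshold over all genes or adjusted over the list alone, and limma gave 1 member an unadjusted p under 0.05. ENO1, an enolase, had 817 ± 15.0 FPKM in Y483E and 780 ± 39.1 in Y483F. The median was -0.025 between the replicates 1 and -0.011 in the libraries numbered 4 and 5, where edgeR called 2 of 25 members higher and 3 lower. The sign of the list's median turned to 0.016 without Y483F replicate 1.

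The pentose phosphate, tricarboxylic acid cycle, respiratory chain and hypoxia lists were not called by camera at the stated settings. Of 13 pentose phosphate pathway genes 11 were higher and 2 lower, with a median of 0.072 (adjusted p 0.0773). PGD was at 130 ± 3.97 and 122 ± 3.16 FPKM in Y483E and Y483F, and PRPS1 at 83.3 ± 0.248 and 79.1 ± 4.53. The tricarboxylic acid cycle list had a median of 0.015 with 15 higher and 8 lower (adjusted p 0.644). Its members MDH2, at 90.1 ± 4.08 and 86.8 ± 3.03 FPKM, and CS, at 66.8 ± 1.36 and 67.8 ± 1.56, were close in the 2 lines. Nuclear-encoded respiratory chain genes were higher in 40 of 54 cases, with a median of 0.035 (adjusted p 0.0730). COX4I1 rose adjusted over the list alone and in the authors' table (adjusted p 0.0022), as did ATP5F1A in the authors' table (0.0496), both named after their values were seen. COX4I1 was at 75.8 ± 1.23 and 63.9 ± 2.42 FPKM. The most abundant members were ATP5F1B, at 552 ± 5.63 and 510 ± 40.4, and NDUFS5, at 351 ± 14.0 and 330 ± 10.3. In the libraries numbered 4 and 5 camera called the pentose phosphate list (0.098, adjusted p 0.0126) and the respiratory chain list (0.070, adjusted p 0.0058, with 13 of 55 members called higher and 1 lower by edgeR). It also called both without Y483E replicate 1 (adjusted p 0.0294 and 0.0072) and with no filter (0.0187 and 0.0049), the pentose phosphate list without Y483F replicate 1 (0.0357), and the respiratory chain list with array weights (0.0073) and the batch term (0.0458). Without Y483F replicate 2 the pentose phosphate median was 0.041 (adjusted p 0.290), and without Y483F replicate 1 that of the respiratory chain list was 0.061 (adjusted p 0.0628). With an estimated correlation both lists had an adjusted p = 0.742 over all 6 libraries, and no list passed in the libraries numbered 4 and 5 (lowest adjusted p = 0.612) or without Y483E replicate 1 (lowest adjusted p = 0.260). Hypoxia targets had a median of 0.0026 with 9 higher and 9 lower (adjusted p 0.402). DDIT4, an inhibitor of mTORC1, was at 31.6 ± 6.50 and 21.8 ± 1.04. It was called by DESeq2 (0.54, adjusted p 0.0035) and in the authors' table, which holds the same fold change (0.0040). It was also called by edgeR with the batch term (0.0343) and in the libraries numbered 4 and 5 (6.6e-06), but not by limma or by edgeR without that term (0.306 and 0.163). The hormone gene STC2 was at 24.6 ± 5.67 and 18.2 ± 2.01.

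Of 20 tested genes of the ATF4 list, which covers amino acid supply under the integrated stress response, 20 were higher in Y483E, and the list rose by a median log2 of 0.24 (camera adjusted p 3.4e-07, but adjusted p = 0.742 with an estimated correlation and 0.412 by fry). No member passed the threshold over all genes or adjusted over the list alone, with 11 at an unadjusted p under 0.05. ATF4 itself was at 309 ± 34.7 FPKM in Y483E and 273 ± 9.43 in Y483F, and the serine synthesis enzyme PSAT1 at 146 ± 21.3 and 111 ± 17.8. Cytosolic ribosomal protein genes rose by a median of 0.090, with 53 of 56 higher (adjusted p 1.2e-07, but adjusted p = 0.742 with an estimated correlation and 0.412 by fry). RPS2 was at 1307 ± 25.1 and 1279 ± 37.2 FPKM, and RPL8 at 911 ± 36.9 and 839 ± 8.24. All 13 mitochondrially encoded genes were lower, with a median of -0.69 (adjusted p 3.4e-07, but adjusted p = 0.742 with an estimated correlation and 0.412 by fry). MT-CO1 was at 2538 ± 766 and 4039 ± 1145 FPKM and MT-CO2 at 2621 ± 768 and 3924 ± 802. The direction of MT-CO2 flipped under quantile normalization, which sets each value by its rank in the library. MT-CO2 lay above MT-CO1 in the Y483E libraries and Y483F replicate 1, but below it in Y483F replicates 2 and 3. Under this setting the list of mitochondrially encoded genes stayed lower and past the threshold (camera adjusted p 0.000281).

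These 3 differences lay in the libraries numbered 4 and 5. Between the replicates 1, Y483E minus Y483F was -0.082 for the ATF4 list, -0.013 for ribosomal proteins and 0.12 for mitochondrially encoded genes. In the libraries numbered 4 and 5 it was 0.39, 0.14 and -1.11. The interaction of line and number, chosen after the data had been seen and with 1 library per line numbered 1, passed camera for these 3 lists (adjusted p 2.3e-17, 5.1e-14 and 2.5e-06), and adjusted p = 0.600 for each with an estimated correlation. It passed at the preset correlation for 9 of 33 lists in all, the others being pentose phosphate, tricarboxylic acid cycle, respiratory chain, hypoxia, fatty acid synthesis and neuronal markers. By gene, with 2 residual degrees of freedom, edgeR called 347 of 17280 genes for this interaction and limma 8 of 12833. In the libraries numbered 4 and 5 edgeR called 18 of 23 ATF4 list genes higher, 35 of 56 ribosomal protein genes higher and 13 of 13 mitochondrially encoded genes lower, and none in the opposite direction. In these libraries PSAT1 was higher by 0.64 ± 0.036 (SE, edgeR adjusted p 1.4e-07) and ATF4 by 0.29 ± 0.040 (adjusted p 0.00026). Neither was called by edgeR over all 6 libraries (adjusted p 0.211 and 0.354). Between the replicates 1 both were lower in Y483E, by -0.12 and -0.072. Mitochondrially encoded reads were 2.11, 2.15 and 1.23% of the total in Y483E replicates 1 to 3, and 2.05, 3.27 and 3.11% in Y483F. Small nucleolar RNA genes, a group chosen after the data had been seen and mostly without poly-A tails, lay at -0.19, -0.10 and -0.33 from the mean of the 6 libraries in Y483E and at -0.083, 0.35 and 0.26 in Y483F, so the libraries highest and lowest in them were also highest and lowest in mitochondrially encoded genes. Without Y483E replicate 3, the library lowest in them, the median of that list was -0.39, and without Y483E replicate 2 that of ribosomal proteins was 0.056.

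**Figure D2:**
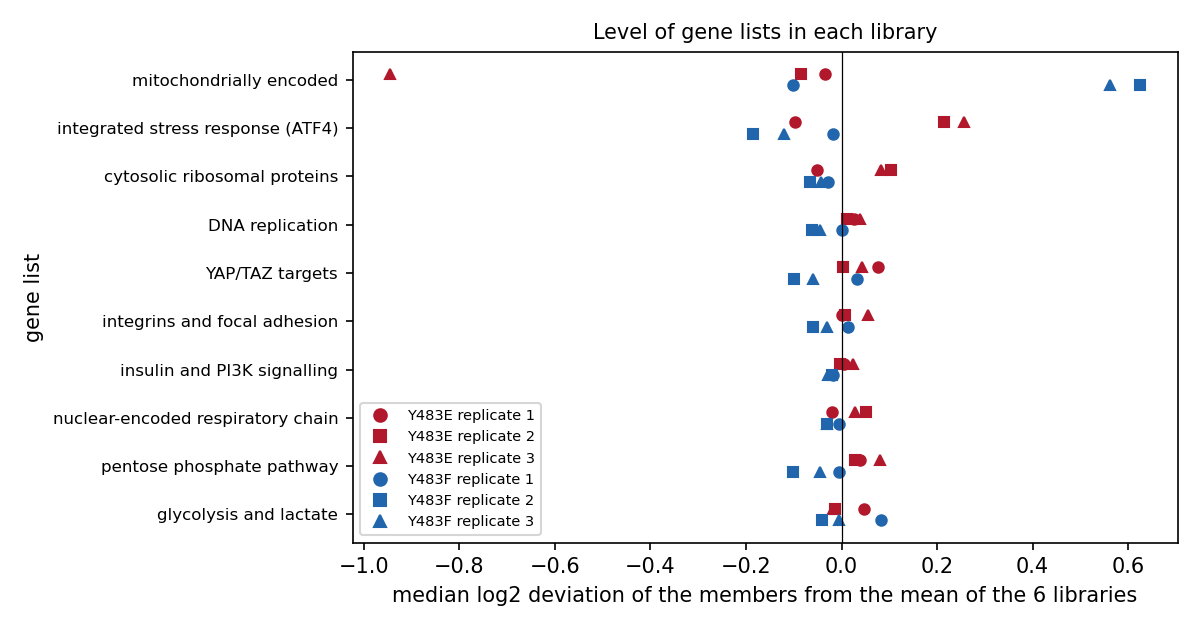
Median log2 deviation of the members of each gene list (vertical axis) from the mean of the 6 libraries (horizontal axis); red is Y483E, blue is Y483F, and circles, squares and triangles are replicates 1, 2 and 3. For mitochondrially encoded genes Y483F replicates 2 and 3 lay at 0.62 and 0.56 and Y483E replicate 3 at -0.94. The replicates 1 lay at -0.034 in Y483E and -0.10 in Y483F, and Y483E replicate 2 lay between them at -0.085.

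Among lists on growth and adhesion, camera called DNA replication and YAP/TAZ targets, both by small margins. DNA replication genes rose by a median of 0.049, with 18 of 27 higher (adjusted p 0.0430, and adjusted p = 0.742 with an estimated correlation). PCNA was at 259 ± 12.3 and 259 ± 2.75 FPKM, MCM7 at 259 ± 4.10 and 237 ± 2.57, and GINS2, which passed adjusted over the list alone and was named after its values were seen, at 25.5 ± 0.420 and 21.3 ± 1.26. YAP/TAZ targets rose by 0.091, with 14 of 16 higher (adjusted p 0.0420, and adjusted p = 0.742 with an estimated correlation). GADD45A was at 25.7 ± 1.72 and 24.1 ± 1.67 FPKM and FJX1 at 20.3 ± 0.966 and 18.8 ± 1.13. The DNA replication call ended without any 1 of the libraries other than Y483E replicate 1, with the filter at 5 FPKM, quantile normalization, no trend and array weights. The YAP/TAZ call ended without Y483E replicate 1 (median 0.057) and without Y483F replicate 2 (0.074), in the libraries numbered 4 and 5 (adjusted p 0.0597), with array weights (0.0726) and with the filter at 5 FPKM. Both calls ended after a correction of each library for GC content and gene length (adjusted p 0.0773 each). Between the replicates 1 the medians were 0.0049 for DNA replication and 0.077 for YAP/TAZ targets, against 0.082 and 0.094 in the libraries numbered 4 and 5.

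Integrin and focal adhesion genes, the structures tensins belong to, had a median of 0.051 with 21 of 26 higher (adjusted p 0.0873), and camera called them in the libraries numbered 4 and 5 (0.094, adjusted p 0.0330), without Y483E replicate 1 (0.066, adjusted p 0.0367) and with no filter (0.0456). The median was 0.030 without Y483E replicate 3 and 0.031 without Y483F replicate 2 (adjusted p 0.353 and 0.257), and over all 6 libraries adjusted p = 0.742 with an estimated correlation. ACTN4 was at 132 ± 4.33 and 128 ± 1.90 FPKM, and ITGB1 at 40.6 ± 1.72 and 38.8 ± 3.04. Extracellular matrix genes had a median of 0.096 with 13 of 20 higher (adjusted p 0.0873). The call was made without Y483E replicate 1 (0.0118) and with no filter (0.0242), and the median was 0.058 without Y483E replicate 3 and 0.052 without Y483F replicate 1. With an estimated correlation the list had an adjusted p = 0.742. The basement membrane genes LAMC1 and NID1 were at 35.9 ± 1.94 and 33.1 ± 3.54 FPKM in Y483E and at 32.6 ± 0.643 and 28.9 ± 0.976 in Y483F. Insulin and PI3K signalling genes had a median of 0.043 with 21 of 33 higher (adjusted p 0.359), and 0.022 without Y483E replicate 1. IRS4 was at 153 ± 0.980 and 165 ± 8.18, and EIF4EBP1, a repressor of translation, at 169 ± 29.9 and 126 ± 7.33 FPKM. EIF4EBP1 was called by DESeq2 (0.42, adjusted p 0.0085) and in the authors' table, which holds the same fold change (0.0096). It was also called by edgeR in the libraries numbered 4 and 5 (4.0e-07), but not by limma or edgeR over all 6 libraries (0.323 and 0.175).

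At the stated settings the other 20 lists were not called by camera, and 0 of their members passed over all genes in limma. Lipid lists had medians of 0.073 for cholesterol synthesis (adjusted p 0.0773) and 0.075 for fatty acid synthesis (0.205), and lysosome and autophagy genes had 0.081 (0.192). Stress lists had -0.023 for endoplasmic reticulum chaperones (0.450), -0.049 for cytosolic heat shock (0.189), -0.034 for p53 targets (0.192) and 0.047 for NRF2 targets (0.702). Mitosis genes had -0.0020 (0.622), actin and SRF targets 0.036 (0.374), immediate early genes -0.025 (0.874) and ERK feedback genes -0.015 (0.564). Signalling lists had -0.094 for NF-kB (0.189), -0.012 for interferon-stimulated genes (0.573), -0.0045 for WNT (0.573), -0.0051 for Notch (0.840) and -0.050 for TGF-beta and BMP targets (0.702). Identity lists had -0.0077 for HOX genes (0.573), 0.046 for neuronal markers (0.374), 0.036 for epithelial markers (0.622) and 0.10 for fibroblast and mesenchymal markers (0.0873). Without Y483E replicate 1 camera called cholesterol synthesis (0.14, adjusted p 0.00059), fatty acid synthesis (0.087, 0.0062), cytosolic heat shock (-0.087, 0.0122), neuronal markers (0.11, 0.0367) and mesenchymal markers (0.15, 0.0294). It also called cholesterol synthesis and mesenchymal markers without Y483F replicate 3 (0.098 and 0.13, adjusted p 0.0451 and 0.0460). In the libraries numbered 4 and 5 it called cholesterol and fatty acid synthesis (0.11 each, adjusted p 0.0088 each). Over all 6 libraries it called cholesterol synthesis with no filter, the replicate block and the batch term (0.0242, 0.0252 and 0.0181), lysosome genes with no filter (0.0404) and mesenchymal markers with the filter at 5 FPKM (0.0192). Without other libraries some medians moved. Cholesterol synthesis had 0.043 and 0.045 without Y483E replicates 2 and 3, fatty acid synthesis 0.030 without Y483E replicate 3 and 0.048 without Y483F replicate 2, and neuronal markers 0.011 and 0.017 without Y483E replicates 2 and 3. Cytosolic heat shock had -0.0045 and -0.032 without Y483E replicates 2 and 3 and -0.021 without Y483F replicate 1, p53 targets had -0.017 and -0.013 without Y483F replicates 2 and 3, NF-kB targets had -0.056 without Y483E replicate 2, mesenchymal markers had 0.068 without Y483E replicate 3, and lysosome genes had 0.052, 0.034 and 0.046 without Y483E replicate 3, Y483F replicate 2 and Y483F replicate 3. Actin and SRF targets had 0.059 and 0.019 without Y483E replicates 2 and 3. No list passed with an estimated correlation in any of these fits, with a lowest adjusted p = 0.260. The median and the test differed in sign for Notch and TGF-beta targets, and the median and the mean for immediate early and Notch genes. Adjusted over the list alone, limma called DUSP5 lower among ERK feedback genes, NCAM1 higher among neuronal markers, and CDH2 and TWIST1 higher and SNAI1 lower among mesenchymal markers, named after their values were seen. Too few members were tested of clustered protocadherins (2, the highest PCDHGC3 at 3.12 FPKM), endothelial markers (1, EGFL7 at 12.9) and blood cell markers (2, the highest CORO1A at 1.57).

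Of the 7 genes called by edgeR, all named after their values were seen, 2 were higher and 5 lower in Y483E. ABCA12 (ENSG00000144452, chromosome 2, 214931542 to 215138428) was at 0.0241 ± 0.00901 FPKM in Y483E and 0.505 ± 0.138 in Y483F, a log2 fold change of -4.41 ± 0.36 (SE, adjusted p 0.00089). It had 5, 3 and 5 reads in the Y483E libraries and 56, 103 and 107 in the Y483F libraries, and AC072062.1, an antisense gene within its span, had 2, 0 and 0 against 15, 21 and 22. CPNE4, a copine, fell by 2.62 ± 0.33 on the log2 scale (adjusted p 0.0248), with 4, 8 and 8 reads against 38, 31 and 47. On chromosome 20, the lysosomal protease gene CTSZ was at 13.4 ± 0.642 and 21.1 ± 2.16 FPKM (-0.66 ± 0.082, adjusted p 0.0248), and the sorting nexin SNX5 at 15.5 ± 0.890 and 20.8 ± 1.11 (-0.43 ± 0.059, adjusted p 0.0339). On chromosome 18, the transcription factor SALL3 was at 1.01 ± 0.0182 and 0.489 ± 0.0345 (1.03 ± 0.14, adjusted p 0.0339), and the tubulin TUBB6 at 30.2 ± 0.833 and 23.3 ± 1.13 (0.37 ± 0.051, adjusted p 0.0339). The 7 genes were also called by edgeR with the batch term and in the libraries numbered 4 and 5 alone, but 1 gene was called without Y483E replicate 2, without Y483E replicate 3 or without Y483F replicate 3, and 3 genes without Y483F replicate 2. ABCA12 was called in each of these fits. With the replicate number as a block, edgeR called 6 genes, of which 4 were among the 7, and SALL3, CPNE4 and AC072062.1 were not (adjusted p 0.0610, 0.0596 and 0.0719). DESeq2 shared 3 of the 7, TUBB6, SNX5 and CTSZ, and gave the others no adjusted p. The authors' table has an adjusted p of 1 for CPNE4 and AC072062.1. SNX5, TUBB6, CPNE4 and ABCA12 overlap other genes, for which strandedness matters, and the calls of ABCA12 and AC072062.1 can rest on reads of 1 locus.

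The authors' table lists 1652 genes, 770 higher and 882 lower in Y483E, of which 126 had an adjusted p under 0.05 (58 higher, 68 lower). By the authors' values, the smallest adjusted p among the higher genes were those of SLC25A6, a mitochondrial ADP/ATP carrier (0.36, 2.8e-06), the cell cycle inhibitor locus CDKN2A (0.29, 2.7e-05) and TUBB6 (0.38, 3.8e-05). Among the lower genes they were those of ABCA12 (-4.44, 1.0e-14), CTSZ (-0.66, 7.4e-07) and SNX5 (-0.42, 2.8e-06). SLC25A6 was at 280 ± 17.2 and 217 ± 6.91 FPKM, and CDKN2A, which overlaps an antisense gene, at 85.6 ± 1.40 and 70.2 ± 0.648. Of the listed genes 1425 were tested by limma, all in the same direction, and 0 passed its threshold. The authors' genes were selected by p-values from the same reads. Agreement in direction, in limma or edgeR, was therefore largely fixed in advance and is no separate support. Of the 126, DESeq2 as run here called 121 and edgeR 5, and edgeR gave all 126 the same direction and an unadjusted p under 0.05. They include 4 ATF4 list genes, named after their values were seen and all higher, the glutathione-degrading CHAC1 (0.97), the serine synthesis enzymes PSPH (0.47) and PHGDH (0.39), and the transcription factor CEBPG (0.28). Of other lists they include COX4I1, ATP5F1A, DDIT4, GINS2, RPL13, TAGLN2, EIF4EBP1, NCAM1 and CDH2, all higher, and BST2, lower (-0.86), also named after their values were seen.

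By chromosome, 6 of 23 passed the threshold. Genes of chromosome 21 fell, with a median log2 fold change of -0.14 (-9.41%) and 87.8% of 139 genes lower (camera adjusted p 5.5e-19, and adjusted p = 0.00763 with an estimated correlation). Those of chromosome 20 fell too, with a median of -0.095 (-6.35%) and 79.7% of 349 genes lower (adjusted p 4.6e-16, and adjusted p = 0.00816 with an estimated correlation). Genes of chromosome 18 rose, with a median of 0.12 (8.72%) and 89.6% of 182 genes higher (adjusted p 4.6e-16, and adjusted p = 0.131 with an estimated correlation). Chromosome 13 (-0.049, adjusted p 0.00012), chromosome 22 (-0.028, 0.0393) and chromosome X (0.032, 0.0393) changed less, and their adjusted p = 0.313, 0.131 and 0.313 with an estimated correlation. In all 6 the median of every library of one line lay on 1 side of those of the other, at an exact permutation p of 0.1 each. The same held for chromosomes 7 and 11, which camera did not call (adjusted p 0.180 and 0.777). Of the authors' 122 adjusted calls that limma tested, which rest on the same reads, 30 lay on chromosomes 18, 20 and 21, which is 24.6% of these calls against 5.22% of the tested genes.

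Between the replicates 1 the medians were 0.067, -0.084 and -0.12 for chromosomes 18, 20 and 21, and in the libraries numbered 4 and 5 they were 0.14, -0.093 and -0.16. In 10 Mb windows with at least 10 tested genes, 8 of 8 on chromosome 18, 7 of 7 on chromosome 20 and 3 of 3 on chromosome 21 went the way of their chromosome. On chromosome 22 the largest window median was -0.14 from 50 Mb on. The medians were smaller with no filter on low values, at 0.032, -0.039 and -0.038 for chromosomes 18, 20 and 21. Chromosome 13 had a median of -0.025 without Y483F replicate 1, and its call ended with no filter (-0.018, adjusted p 0.136). The call of chromosome 22 ended without Y483E replicate 1, Y483E replicate 2, Y483F replicate 2 or Y483F replicate 3, and that of chromosome X without Y483E replicate 2, Y483E replicate 3, Y483F replicate 1 or Y483F replicate 2. The call of chromosome X also ended with the replicate number as a block (adjusted p 0.0541), no filter, the filter at 5 FPKM, quantile normalization and array weights. That of chromosome 22 ended with no filter and with the filter at 5 FPKM (adjusted p 0.136 and 0.0994), and after the correction for GC content and gene length (0.0515).

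**Figure D3:**
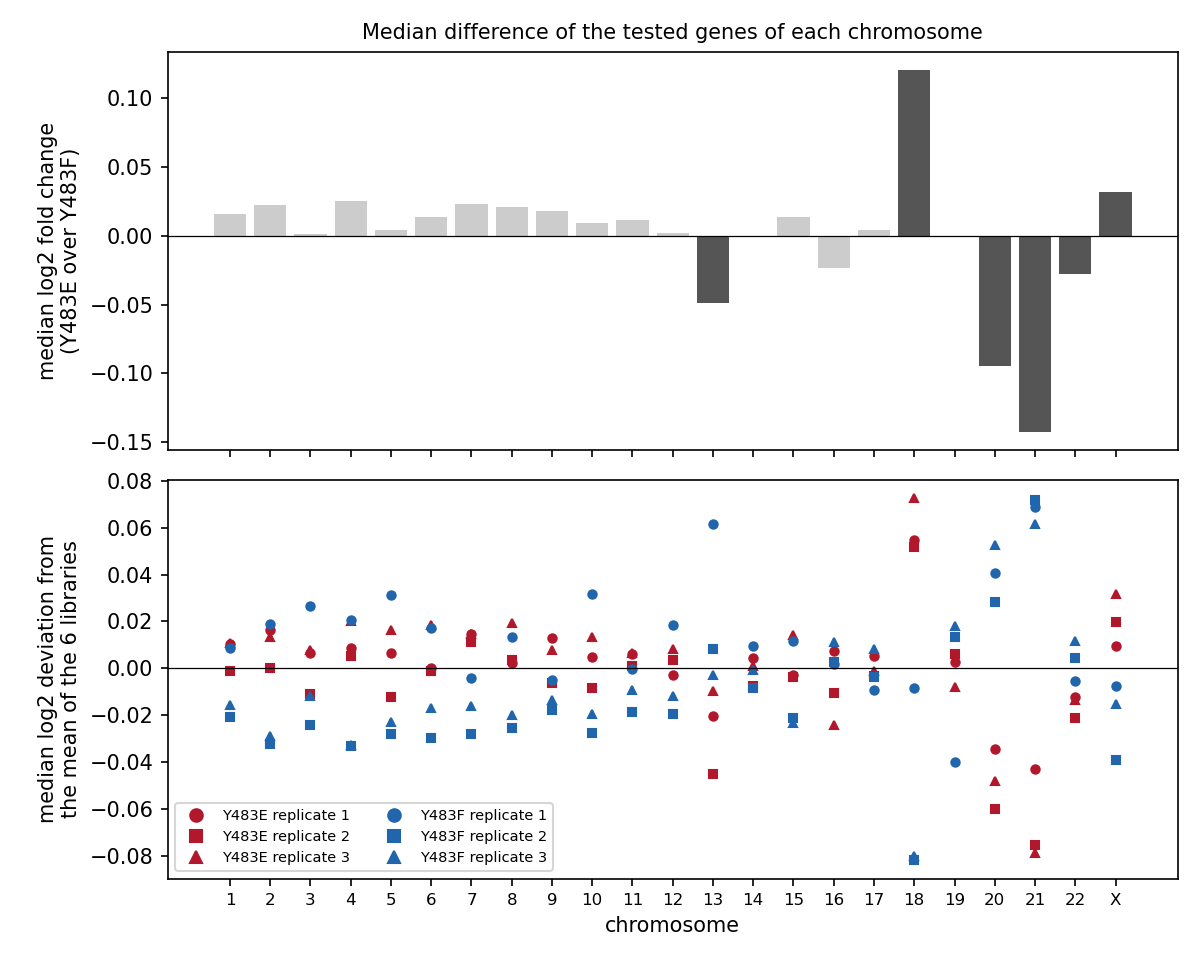
Top, median log2 fold change (Y483E over Y483F) of the tested genes of each chromosome, with dark bars for adjusted p under 0.05 by camera; bottom, the median log2 deviation of each library from the mean of the 6 libraries, with red for Y483E, blue for Y483F and circles, squares and triangles for replicates 1, 2 and 3. Chromosome 18 stands above and chromosomes 20 and 21 below 0.

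**Figure D4:**
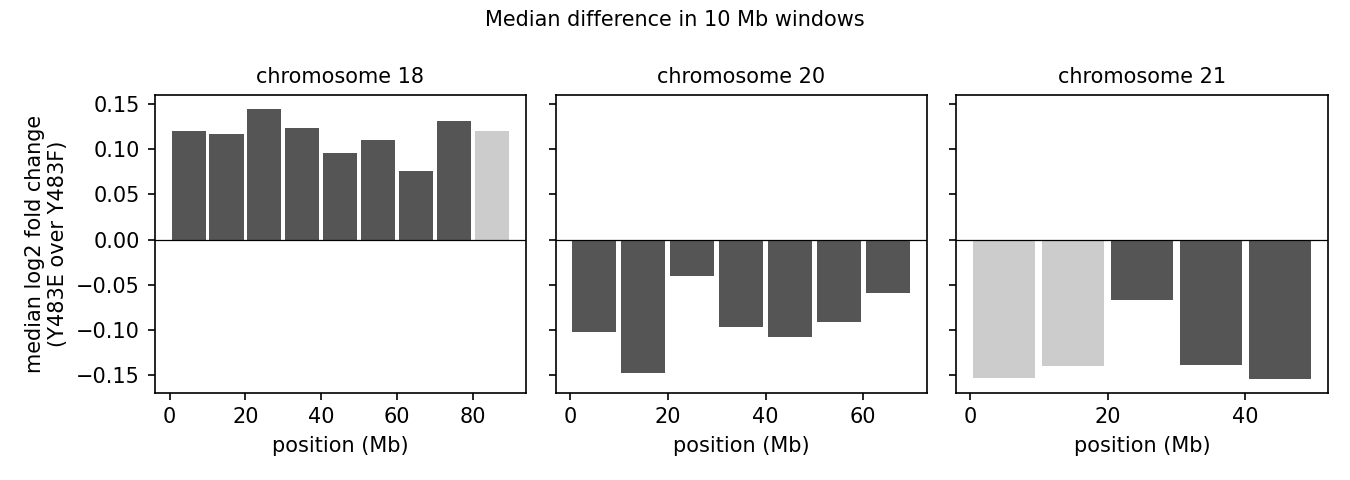
Median log2 fold change (Y483E over Y483F) in 10 Mb windows along chromosomes 18, 20 and 21, with dark bars for windows with at least 10 tested genes. The dark bars range from 0.076 to 0.14 on chromosome 18, from -0.15 to -0.040 on chromosome 20 and from -0.15 to -0.067 on chromosome 21.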

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

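The batch term, the libraries numbered 4 and 5 alone, the edgeR and DESeq2 fits, and an estimated correlation in fits other than the stated one were chosen after the data had been seen, and the other settings before. Over 84 reported results, 1344 recomputed values kept their direction and their side of the threshold or moved little, 55 came past the threshold, 65 fell short of it, 31 counts moved by more than 1.5 times and 48 values changed sign. The values that changed sign belonged to lists and genes that had not passed the threshold. The ATF4, ribosomal protein and mitochondrially encoded lists and chromosomes 18, 20 and 21 passed in 19 of 19 camera fits at the preset correlation, chromosome 13 in 18, YAP/TAZ targets in 14, chromosome 22 in 13, and DNA replication and chromosome X in 10. Genes past the threshold numbered 1888 with array weights, 733 in the libraries numbered 4 and 5 only, 7 by edgeR and 142 by DESeq2. Those changed at least 2-fold numbered 44, 34, 4 and 1, and the authors' listed genes among the calls 1127, 536, 7 and 142. Among protein-coding genes, adjusted over these alone, calls of at least 2-fold numbered 2 with array weights and 3 in the libraries numbered 4 and 5 only. Array weights gave Y483F replicate 1 a weight of 0.288 and Y483F replicate 3 one of 4.60. Gene lists past the threshold numbered 11 with no filter, 9 in the libraries numbered 4 and 5 only, 0 with an estimated correlation (also 0 in each of 12 other fits), 0 by fry, and 3 to 13 when 1 library was left out. The mixed test of fry, which covers changes in either direction, passed for DNA replication and extracellular matrix (adjusted p 0.0417 each) and for mesenchymal markers (0.0393). Chromosomes numbered 3 with no filter and 2 with an estimated correlation. The edgeR count of 7 became 142 with DESeq2, 14 with no TMM, 671 with no filter, 169 with the batch term, 2454 in the libraries numbered 4 and 5 only, and 1 to 1000 when 1 library was left out. With the replicate number as a block, limma called 0 genes, 6 lists and 5 chromosomes, X being lost, and edgeR 6 genes. Of these 6 genes 4 were among the 7. The residual correlations between libraries of the same number were 0.056, 0.14 and -0.095, so the numbers were not taken as pairs, although the libraries numbered 1 lay close to each other. TNS2 kept its direction in every fit and has no value under the filter at 5 FPKM, which it does not pass.

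Some medians near 0 changed sign. With the filter at 5 FPKM, and so with fewer members, they were 0.0073 for glycolysis, -0.0054 for extracellular matrix, 0.033 for interferon-stimulated genes and 0.11 for Notch. With no filter they were -0.0059 for hypoxia, 0.0019 for ERK feedback, 0.036 for WNT and -0.011 for neuronal markers. Median-of-ratios scaling gave -0.0069 for hypoxia. Quantile normalization gave 0.0030 for ERK feedback, 0.011 for Notch, 0.055 for MT-CO2 and -0.0092 for ACTN4. Array weights gave 0.0069 for mitosis, 0.043 for Notch and 0.0056 for PCNA. The libraries numbered 4 and 5 only gave 0.013 for mitosis, 0.031 for ERK feedback, 0.023 for Notch and 0.033 for PCNA. Leaving out 1 library gave -0.045 to 0.016 for glycolysis, -0.022 to 0.064 for the tricarboxylic acid cycle, -0.0017 to 0.058 for hypoxia, -0.054 to 0.0066 for endoplasmic reticulum chaperones and -0.039 to 0.043 for mitosis. It gave -0.13 to 0.063 for immediate early genes, -0.13 to 0.072 for ERK feedback, -0.062 to 0.00088 for interferon-stimulated genes, -0.037 to 0.012 for WNT and -0.0095 to 0.046 for Notch. It gave -0.17 to 0.029 for TGF-beta and BMP targets, -0.013 to 0.060 for NRF2 targets, -0.011 to 0.0022 for HOX genes, -0.020 to 0.042 for epithelial markers and -0.035 to 0.034 for PCNA. For MT-CO2, its rank against MT-CO1 differed between libraries, as given above. Apart from this and the smaller sets of genes or libraries named, the cause was not tested. Depth limits genes with few reads, such as TNS1.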

Other observations

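The gene groups in this paragraph were chosen after the data had been seen, and their adjusted p-values from camera cover only these groups. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were higher in Y483E in 15 of 20 cases, with a median log2 fold change of 0.15 (adjusted p 3.3e-05, and adjusted p = 0.401 with an estimated correlation). The rise lay in replicates 2 and 3, at 0.11 and 0.14 from the mean of the 6 libraries in Y483E and -0.16 and -0.13 in Y483F. The replicates 1 lay at 0.029 in Y483E and 0.042 in Y483F. Small nucleolar RNA genes were lower in 47 of 61 cases, with a median of -0.36 (adjusted p 8.7e-07, and adjusted p = 0.207 with an estimated correlation), and Y483F replicates 2 and 3 lay highest, at 0.35 and 0.26 from the mean of the 6 libraries. Antisense transcripts had a median of -0.067 with 278 of 450 lower (adjusted p 0.00023, and adjusted p = 0.401 with an estimated correlation), and ZNF genes -0.043 with 260 of 376 lower (adjusted p 0.00023, and adjusted p = 0.207 with an estimated correlation). The replicates 1 of Y483E and Y483F barely differed, at -0.042 and -0.044 for antisense transcripts and -0.0056 and -0.0058 for ZNF genes. Y483F replicates 2 and 3 lay highest, at 0.10 and 0.065 for antisense transcripts and 0.032 and 0.028 for ZNF genes. Histone, mitochondrial ribosomal protein and proteasome genes had medians of -0.0044, 0.017 and 0.020 and were not called.

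In what follows, the tests on windows, on the libraries numbered 4 and 5, their interaction, a mislabelled library and an estimated correlation after the correction below were chosen after the result was seen, and those on GC content and gene length and on other splits before. The first pattern is the shift of chromosomes 18, 20 and 21. After a correction of each library for GC content and gene length these kept at least 97.6% of their medians and stayed past the threshold (with an estimated correlation adjusted p = 0.0411, 0.0295 and 0.0295), which argues against such a bias as the whole cause. A difference in DNA copy number between the lines may underlie the shift. Of the 18 windows with at least 10 genes 100% went the way of their chromosome, and the replicates 1 showed the same directions. The chromosomes were picked from these same values, with most of their genes going 1 way. The windows could therefore hardly go otherwise, and they do not set copy number apart from other causes. The medians are smaller than the loss of 1 of 3 copies (-0.58 on the log2 scale), the loss of 1 of 4 (-0.42) or the gain of 1 over 3 (0.42) in every cell, so a copy change in part of the cells, a dampened response of transcripts and an effect of the mutation stay open. No DNA was measured here.

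The second pattern is the higher ATF4 targets and ribosomal proteins and the lower mitochondrially encoded genes in Y483E. After the correction for GC content and gene length the medians kept 95.2%, 94.4% and 95.6% and stayed past the threshold at the preset correlation, which argues against that bias as the whole cause, though adjusted p = 0.659 for each with an estimated correlation. Whether Y483F replicate 1 is a mislabelled Y483E library was asked on chromosomes 20 and 21. Its lower position there was 0.999, with 0 at the Y483E mean and 1 at that of the other Y483F libraries. Both chromosomes were picked with this library counted as Y483F, which favours such a position. They also passed camera at the preset correlation without it, so the position was not wholly fixed in advance. It argues against mislabelling for the genes of these chromosomes only. On chromosome 18, which the test left out, the position was 0.483. Over the 1000 genes that edgeR called without this library its median was 0.191, with 23.3% of them closer to the other Y483F libraries. In 3 of 3 lists the difference between the replicates 1 was under 25% of that in the others or had the opposite sign. Y483F replicate 1 lay within the Y483E range, and Y483E replicate 1 within the Y483F range. These values prompted the question and rest on 1 library per line. The interaction passed for the lists only at the preset correlation, and for 347 of 17280 genes in edgeR but 8 of 12833 in limma. A state of the libraries numbered 4 and 5 and an effect of the mutation therefore cannot be told apart. A difference in RNA quality or poly-A selection stays open for the mitochondrially encoded genes, since small nucleolar RNA genes moved in the same libraries.

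TNS2 was low in lines made to express it. Its mean of 1.04 FPKM lies at percentile 37.0 of protein-coding genes with reads, and 96.4% of its coding bases are free of exons of other genes. Whether the construct's sequence differs from the human gene or its expression is low was not tested, and no untransfected library was analysed here.

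Splitting the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. By limma the real split gave 0 genes and 0 at 2-fold, against at most 2 and 2 in the others. So 10 and 10 of the 10 splits gave as many, which a real count of 0 fixes in advance and which therefore decides nothing. For gene lists 6 splits gave as many as the real 5, with a highest other of 16 when the replicates 1 of both lines and Y483F replicate 3 were set against the rest. For chromosomes 2 splits gave as many as the real 6, the other being Y483E replicate 1 with Y483F replicates 2 and 3, which also gave 6. The real 7 genes of edgeR were reached by 1 split, the real one, against at most 1 gene in the others. For DESeq2 2 splits gave as many as the real 142, with 195 when Y483E replicates 1 and 3 and Y483F replicate 1 were set against the rest, a split that also puts the replicates 1 together. With the batch term the real split gave 7 lists, and edgeR called 169 genes. After the correction for GC content and gene length limma called 1 gene, 3 lists and 5 chromosomes, the calls of DNA replication, YAP/TAZ targets and chromosome 22 being lost, with 1692 genes at an unadjusted p under 0.05.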
